A study of Rattus norvegicus with 62 samples.

How the data were processed

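The deposited values are estimated counts per gene: reads shared between genes or places enter as fractions, and 74.2% of nonzero values in the first and 78.2% in the second count table are whole. They were rounded to integers before edgeR, which moved a library total by at most 0.0108%. The analysis plan written before the data were examined had named the unit as counts, and the fractional values made estimated counts the unit used. The labels state RNA with an integrity number of at least 7.5, 300 to 500 ng of input, poly-A selection, 13 to 15 PCR cycles and single-end reads, 75 nt on a NextSeq 500 or 100 nt on a NextSeq 2000, without saying which library was read on which. The submitters' notes name bcl2fastq 2.20.0.422, cutadapt 2.5, STAR 2.7.2b and featureCounts 1.6.4 with the genome build mRatBN7.2, and 40982 genes are counted in each table. Own steps used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and pandas 2.3.3. Gene coordinates are those of the count tables.

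The first table holds the male 1 and 5 week libraries (24 libraries, 18.9 to 33.5 M counts) and the second the female and the male 24 h libraries (38 libraries, 16.9 to 26.6 M counts). Sex is therefore tied to table except at 24 h, and table, sequencing run and sex cannot be separated at 1 and 5 weeks. No library was dropped, no 2 libraries were duplicates, and Y-linked genes were counted in every male library. Reads were counted on whole ganglia, so changes in cell numbers and changes within cells are not told apart, and genes with few counts in small groups are measured least well.

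Before the data were examined the following was fixed: TMM scaling, genes kept by filterByExpr per group with a minimum count of 10, the robust quasi-likelihood test of edgeR on a group design per table, a joint fit of both tables for comparisons across them, Benjamini-Hochberg adjusted p under 0.05, 28 gene lists and other settings to try. Standard errors are the absolute log2 fold change divided by the square root of F. Values per library are counts per M on scaled library sizes, given as mean with SD. Lists were tested with camera of limma at the preset correlation of 0.01, and beside it with an estimated correlation and with fry. Counts of list members are given over all genes tested and adjusted over the list alone. The lists reported here are nerve injury genes, cholesterol synthesis, cytokines, immediate early genes, cell cycle, potassium channels, sodium and calcium channels, sensory neuron subtype markers, macrophage, MHC class II, complement, neutrophil and mast cell, erythrocyte, B cell, muscle and adipocyte, satellite glia, extracellular matrix, myelin and repair Schwann cell genes.

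Genes were named by rule: Atf3, Gal, Npy, Sprr1a, Gap43 and the sex-linked genes as a check of the labels; the 8 largest increases and 8 largest decreases of each comparison of sides among genes with adjusted p under 0.05, mean log2 CPM of at least 1, the same sign in every pair and a gene symbol; the 8 smallest p-values per direction of each other comparison; and the 4 smallest p-values of each list described. The text leaves out members of the last 3 kinds. Oprm1 and Kcnb2, in comparisons where the rule does not name them, were chosen after their values were seen.

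For the libraries of the second table the same animal code is recorded for both sides. In both tables the same-numbered libraries of both sides were correlated after group means were removed. Median correlations of same-numbered libraries were 0.202 for male 24 h, 0.405 for male 1 week, 0.274 for male 5 weeks, 0.276 for female 1 week and 0.294 for female 5 weeks, so sides were treated as paired in the alternative with replicate number as a block. That block gave 3142, 10230, 7784, 8963 and 8336 genes for these 5 comparisons of sides. At 24 h the ipsilateral library of number 6 correlated with the contralateral library of number 5 (0.23), and a block with these numbers crossed gave 3298 genes.

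A self-test simulated counts with the real depths, mean levels and dispersions and placed known changes in them. At a 1.5-fold change 62% of changed genes were found with the male 5 week group sizes and 80% with those of females at 1 week, with 3 and 4 false calls. Changes of 1.25-fold were found in 28% and 40%. At most 50 genes were changed per size of change, far fewer than were called in the real comparisons, and sides were not paired. The adjustment of p-values was therefore stricter there, and these shares do not measure how many real differences were missed. Differences between weeks were not simulated. GC content was not used here.

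After the data were seen, settings with the share of ribosomal RNA as covariate, with ribosomal RNA genes left out, with an exon length trend removed, with the contralateral libraries of the other week, with the crossed block and with the mean of both weeks were added. They are marked as chosen after seeing the data. Intervals marked as over animals come from 1000 draws of replicate numbers within each group of sex and week, which stand for animals.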

Results

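Dorsal root ganglia hold the cell bodies of sensory neurons together with satellite glia, Schwann cells, vessels and immune cells. Poly-A RNA of rat L4 ganglia was counted per gene after chronic constriction injury of the sciatic nerve, a model of neuropathic pain. Ganglia of the injured (ipsilateral) side were set against those of the opposite (contralateral) side in males at 24 h (6 and 6 libraries), 1 week (7 and 7) and 5 weeks (5 and 5), and in females at 1 week (7 and 7) and 5 weeks (6 and 6). The question was which genes answer the injury, how the answer changes with time, and whether it differs between the sexes. The 62 libraries held 16.9 to 33.5 M counts each. The p-values measure spread between these samples, which the labels do not tie to separate animals for males at 1 and 5 weeks. The Y-linked genes Kdm5d and Eif2s3y matched the labelled sex in every library. Kdm5d averaged 25.6 to 31.9 CPM in male groups and had 0 counts in each female library, where up to 3 counts remain possible.

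The known response of sensory neurons to nerve injury was present in every comparison. Atf3, a transcription factor switched on in injured neurons (GeneID 25389, chromosome 13, 102751278 to 102800520 in mRatBN7.2), rose in males by a log2 fold change of 4.74 (SE 0.214) at 24 h, 4.80 (SE 0.147) at 1 week and 4.46 (SE 0.174) at 5 weeks. In females it rose by 5.27 (SE 0.205) and 4.58 (SE 0.217). Sprr1a, a growth-associated gene, was near the counting floor on the contralateral side and rose in all 5 comparisons (at 24 h adjusted p = 0.0966 with limma-voom). Gap43, a growth cone protein gene (chromosome 11, 58376371 to 58470047), rose by 0.36 (SE 0.0904) at 24 h, by 1.52 (SE 0.0721) in males and 1.75 (SE 0.0853) in females at 1 week. At 5 weeks it rose by 1.59 (SE 0.0857) in males and 1.45 (SE 0.0915) in females. The neuropeptide gene Npy (chromosome 4, 78881294 to 78888495) was unchanged at 24 h (log2 fold change -0.55, SE 0.544, adjusted p = 0.57). It went from 0.735 CPM (SD 0.297) to 281 CPM (SD 63.8) in males at 1 week. Gal, which encodes galanin (chromosome 1, 200650439 to 200655302), rose by 1.15 (SE 0.306) at 24 h (adjusted p = 0.00866, but 0.102 with limma-voom), by 4.89 (SE 0.198) and 4.79 (SE 0.249) in males at 1 and 5 weeks, and by 3.91 (SE 0.284) in females at 5 weeks.

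**Figure D1:**
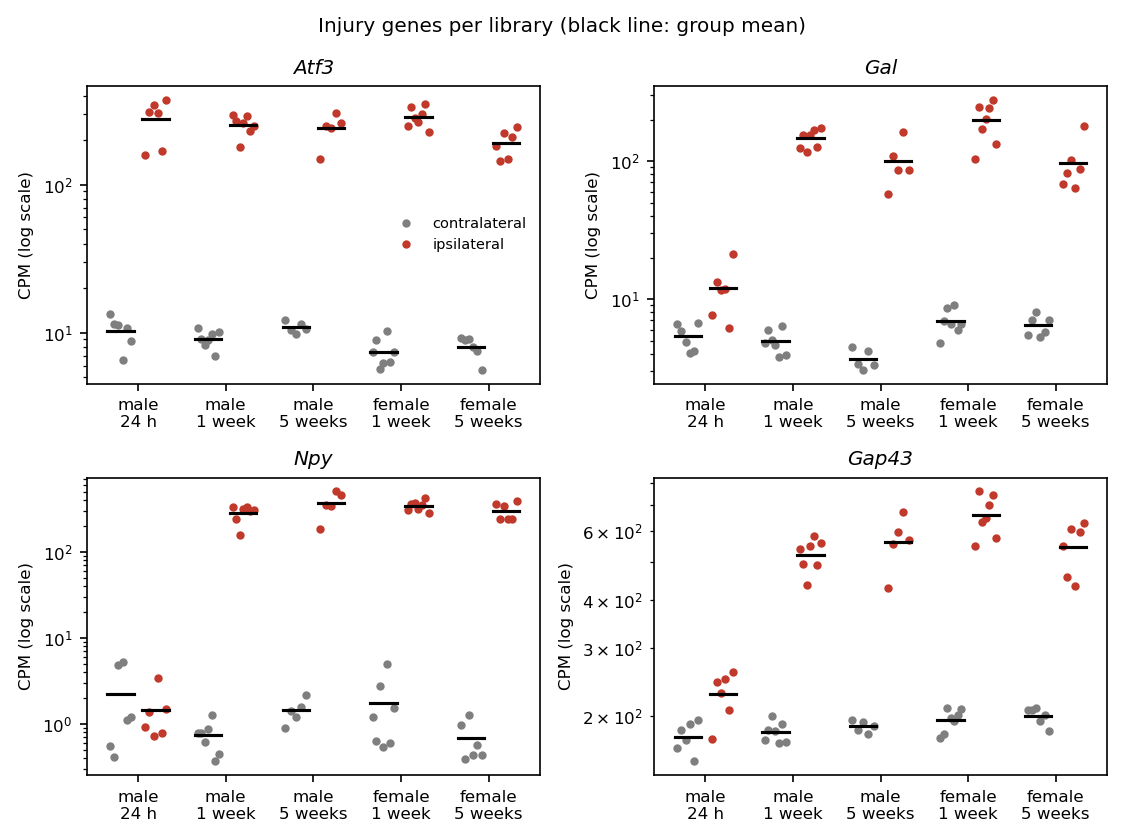
CPM of injury genes in each library, by arm and side.

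Within 24 h nerve injury genes, many cholesterol synthesis genes and some cytokine genes rose in the injured male ganglion, and some cell cycle and potassium channel genes and an opioid receptor fell. Reg3b, a secreted lectin, rose by 4.52 (SE 0.491), Alkal2, a ligand of the receptor ALK, by 4.15 (SE 0.279), and Sox11, a transcription factor of growing neurons, by 3.26 (SE 0.198), each in 6 of 6 pairs. Gadd45a, a stress response gene, rose by 2.73 (SE 0.151). Oprk1, the kappa opioid receptor, fell by -1.34 (SE 0.253), and the transcription factor Onecut1 fell in 6 of 6 pairs. Of 18135 genes tested, 2556 differed between sides, 1487 higher and 1069 lower, and 1597 when these 2 groups were fitted alone. Mmp13, a collagenase gene, fell by -2.45 (SE 0.827, adjusted p = 0.0424) and Acp5, an osteoclast and macrophage phosphatase gene, by -1.09 (SE 0.332, adjusted p = 0.0229). With replicate number as a block their adjusted p-values were 0.113 and 0.0629, with the 2 groups alone 0.125 and 0.199, and with limma-voom 0.177 and 0.0798. The fall of Mmp13 was smaller with the block (-1.59) and with limma-voom (-1.48), and its contralateral SD (12.4 CPM) exceeded its mean (7.69 CPM). Mmp13 also lost its call without a filter (0.0754) and with the ribosomal RNA share as covariate (0.0756).

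In the list of nerve injury genes, 29 of 43 rose at 24 h (31 adjusted over the list alone; set test adjusted p = 3.66e-29, and adjusted p = 0.0036 with an estimated correlation). Of the cholesterol synthesis genes 16 of 25 rose (20 adjusted over the list alone), among them Insig1 by 0.60 and Mvd by 0.62. The set of cholesterol genes had adjusted p = 2.86e-12, and adjusted p = 0.409 with an estimated correlation. Cytokine genes rose in part, 8 of 30 higher and 1 lower (8 and 3 adjusted over the list alone), led by Il6, Ccl2 at 2.06 and Csf1 at 1.17. The set of cytokines had adjusted p = 0.029, and adjusted p = 0.753 with an estimated correlation. Of the immediate early genes 8 of 17 rose and 1 fell (10 and 2 adjusted over the list alone), Socs3 by 2.63 and Junb by 1.02. The set of immediate early genes had adjusted p = 3.26e-05, and adjusted p = 0.409 with an estimated correlation. Cell cycle genes went down, 10 of 35 over all genes and 19 adjusted over the list alone, Ccna2 by -0.98 and Mki67 by -1.20 (adjusted p = 0.0115, but 0.209 when the 2 groups were fitted alone and 0.0589 with the block). The set of cell cycle genes had adjusted p = 3.97e-06, but adjusted p = 0.753 with an estimated correlation and 0.0736 with fry. Potassium channel genes, which set resting excitability, already fell in 7 of 38 (10 adjusted over the list alone), Kcnn2 by -0.65 and Kcna4 by -0.55. The set of potassium channels had adjusted p = 0.000918, but adjusted p = 0.753 with an estimated correlation and 0.0774 with fry. In the same libraries hemoglobin transcripts took 0.0665% (SD 0.042) of ipsilateral and 0.142% (SD 0.113) of contralateral counts, a gap within that spread. The erythrocyte list was lower as a set. The set of erythrocyte markers had adjusted p = 0.01, but adjusted p = 0.856 with an estimated correlation and 0.167 with fry. The pairs differed: erythrocyte markers had a mean of -3.22 in pair 5 and 1.52 in pair 6, neutrophil and mast cell markers -3.29 and 1.87, and cell cycle genes -1.50 and 0.34. Numbers 5 and 6 may not pair as labelled: their sides correlated at 0.0109 and 0.0126, but crossed, ipsilateral 6 with contralateral 5 at 0.228 and ipsilateral 5 with contralateral 6 at 0.124. As sets, neutrophil and mast cell markers were lower (adjusted p = 0.01, but adjusted p = 0.819 with an estimated correlation and 0.128 with fry). So were muscle and adipocyte markers (adjusted p = 0.01, but adjusted p = 0.753 with an estimated correlation and 0.0833 with fry). A stricter filter ended both calls (0.0895 and 0.104). Matrix genes were lower too as a set (adjusted p = 0.00399, but adjusted p = 0.894 with an estimated correlation and 0.236 with fry). Their mean was above 0 in 3 of 6 pairs.

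At 1 week in males Npy, Vip and Gal rose, macrophage, MHC class II and cytokine genes rose, and potassium channel and myelin genes fell. Npy rose by 8.56 (SE 0.295), Vip, encoding vasoactive intestinal peptide, by 7.67 (SE 0.328), and Csrp3, a muscle LIM protein gene that is switched on in injured neurons, by 8.15 (SE 0.317). The phosphatase gene Ptprh and the channel adaptor gene Stac2 rose with them, all in 7 of 7 pairs. Adra1a, the alpha-1A adrenergic receptor, fell by -2.20 (SE 0.16), Pla2g7 by -1.83 (SE 0.123), and the GTPase gene Rem2, the perineuronal net gene Hapln1 and the adhesion gene Igsf21 fell with them. In all, 8913 of 18994 genes tested differed, 4476 higher and 4437 lower, of which 884 rose and 195 fell more than 2-fold.

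Nerve injury genes rose in 37 of 43 and fell in 2 (38 and 2 adjusted over the list alone; adjusted p = 2.15e-26, adjusted p = 0.0204 with an estimated correlation). Antigen presentation by MHC class II rose in 12 of 12 genes (12 adjusted over the list alone), Cd74 by 1.84 and RT1-Db1 by 1.69. The set of MHC class II genes had adjusted p = 3.24e-05, and adjusted p = 0.37 with an estimated correlation. Macrophage markers rose in 27 of 35 (27 adjusted over the list alone), Lyz2 by 1.74, Fcgr2b by 1.70 and Cx3cr1 by 1.55. The set of macrophage markers had adjusted p = 2.5e-08, and adjusted p = 0.37 with an estimated correlation. Cytokine genes rose in 20 of 30 (21 adjusted over the list alone), Csf1 by 2.21 and Ccl2 by 1.71 (adjusted p = 3.02e-06, adjusted p = 0.193 with an estimated correlation). Cell cycle genes rose in 27 of 35 (29 higher and 1 lower adjusted over the list alone; adjusted p = 1.34e-06, adjusted p = 0.37 with an estimated correlation). Neutrophil and mast cell markers rose in 14 of 18 (14 adjusted over the list alone; adjusted p = 0.000432, adjusted p = 0.37 with an estimated correlation). In the same libraries all 10 erythrocyte markers rose (10 adjusted over the list alone; adjusted p = 0.00178, adjusted p = 0.462 with an estimated correlation). Hemoglobin transcripts took 0.123% (SD 0.0566) of ipsilateral and 0.0389% (SD 0.0241) of contralateral counts.

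On the neuronal side at 1 week in males, potassium channel genes fell in 28 of 38 and rose in 2 (28 and 2 adjusted over the list alone), Kcna2 by -0.96, Kcnn2 by -0.97 and Kcnk1 by -0.75. The set of potassium channels had adjusted p = 1.95e-09, and adjusted p = 0.193 with an estimated correlation. Markers of sensory neuron subtypes fell in 25 of 37 and rose in 6 (25 and 6 adjusted over the list alone): Ntrk3 by -0.62 and Nefh by -0.68, both of large myelinated neurons, fell, and Gfra3 rose by 0.62. The set of subtype markers had adjusted p = 0.00178, and adjusted p = 0.37 with an estimated correlation. Myelin genes fell in 14 of 22 (14 lower and 1 higher adjusted over the list alone), Pmp2 by -0.89 and Mag by -0.53 (adjusted p = 0.00123, adjusted p = 0.478 with an estimated correlation). Repair Schwann cell genes rose in 12 of 16 and fell in 2 (13 and 2 adjusted over the list alone), Cdkn1a by 2.33 and Runx2 by 1.18 (adjusted p = 0.00123, adjusted p = 0.134 with an estimated correlation).

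At 5 weeks in males Vip and Npy were still high, potassium channel genes were still low, and 6 macrophage markers were higher. Vip rose by 8.77 (SE 0.416), Npy by 7.97 (SE 0.333), Draxin, an axon guidance gene, by 5.08 (SE 0.23) and Cckbr, a cholecystokinin receptor, by 5.04 (SE 0.235), each in 5 of 5 pairs. Adra1a fell by -2.26 (SE 0.198), and Agt, Ckmt2, Klhl14 and Trpm6 fell with it. Of the 18994 genes tested 6589 differed, 3046 higher and 3543 lower (3441 and 2988 of 6429 with a stricter filter), with 5685–6679 when 1 library was left out. Nerve injury genes rose in 36 of 43 and fell in 2 (38 and 2 adjusted over the list alone; adjusted p = 1.95e-29, adjusted p = 0.012 with an estimated correlation). Potassium channel genes fell in 27 of 38 and rose in 2 (27 and 2 adjusted over the list alone), Kcns3 by -1.27 and Kcnn2 by -0.99. The set of potassium channels had adjusted p = 4.59e-09, and adjusted p = 0.249 with an estimated correlation. Repair Schwann cell genes rose in 12 of 16 and fell in 2 (12 and 2 adjusted over the list alone; adjusted p = 0.000206, adjusted p = 0.0367 with an estimated correlation). MHC class II genes rose in 9 of 12 (9 adjusted over the list alone), Cd74 by 1.22. The set of MHC class II genes had adjusted p = 0.00264, and adjusted p = 0.758 with an estimated correlation. Macrophage markers rose in 6 of 35 and fell in 1 (2 higher adjusted over the list alone; adjusted p = 0.0491, adjusted p = 0.914 with an estimated correlation). RLE scaling ended that call at adjusted p = 0.0601, the stricter filter at 0.101 and fry at 0.173.

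In females at 1 week Vip, Npy, macrophage and MHC class II genes rose and potassium channel and myelin genes fell as in males, while Oprm1 and Kcnb2 fell further and Ro60 fell only in females. Vip rose by 8.62, Csrp3 by 8.55, Npy by 7.61 (SE 0.343) and Stac2 by 6.73 (SE 0.223) in 7 of 7 pairs, and Reg3b and Tgm1 rose with them. Adra1a fell by -2.37 (SE 0.175), Oprm1, the mu opioid receptor, by -2.29 (SE 0.163), the potassium channel genes Kcnh7 by -2.00 (SE 0.0978) and Kcnb2 by -1.86 (SE 0.164), and Ro60, which binds small noncoding RNAs, by -1.59 (SE 0.114). In all 8284 of 18135 genes tested differed, 4341 higher and 3943 lower. The ribosomal RNA share of counts was 2.25% (SD 0.359) in contralateral and 0.970% (SD 0.236) in ipsilateral libraries of this arm. With that share as covariate 3936 genes differed. The shares of the 2 sides did not overlap (lowest contralateral 1.69%, highest ipsilateral 1.42%). The covariate is thus tied to side here, and lost precision alone could lower the number. Against the contralateral libraries of the other week, Oprm1 fell by -0.81 (SE 0.179) and Kcnb2 by -0.74, and Ro60 did not differ (log2 fold change 0.14, SE 0.127, adjusted p = 0.382).

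Nerve injury genes rose in 38 of 43 and fell in 3 in females at 1 week (38 and 3 adjusted over the list alone), Ankrd1 by 5.33 and Cckbr by 4.82. The set of nerve injury genes had adjusted p = 8.73e-26, and adjusted p = 0.0076 with an estimated correlation. Potassium channel genes fell in 29 of 38 and rose in 3 (29 and 3 adjusted over the list alone), Kcns1 by -1.18 and Kcna2 by -1.01. The set of potassium channels had adjusted p = 2.83e-11, and adjusted p = 0.183 with an estimated correlation. Sodium and calcium channel genes fell in 22 of 37 and rose in 7 (23 and 9 adjusted over the list alone): Scn1a fell by -0.90 and Scn8a by -0.81, and Scn3b rose by 0.99. The set of sodium and calcium channels had adjusted p = 0.00612, and adjusted p = 0.52 with an estimated correlation. Myelin genes fell in 13 of 22 (13 adjusted over the list alone), Mag by -0.72. The set of myelin genes had adjusted p = 0.00093, and adjusted p = 0.792 with an estimated correlation. Mag did not differ against the contralateral libraries of the other week (0.03, adjusted p = 0.865). With the ribosomal RNA share as covariate its estimate stayed at -0.57 but was no longer called (adjusted p = 0.106). Macrophage markers rose in 22 of 35 (24 adjusted over the list alone), Cx3cr1 by 1.81 and C1qa by 1.62 (adjusted p = 2.73e-05, adjusted p = 0.572 with an estimated correlation). MHC class II genes rose in 12 of 12 (12 adjusted over the list alone; adjusted p = 0.000351, adjusted p = 0.52 with an estimated correlation).

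In females at 5 weeks Npy, Vip, macrophage, complement and matrix genes were higher on the injured side, and potassium channel genes lower. Npy rose by 8.74 (SE 0.421), Vip by 8.32, Draxin by 5.09 and Serpina3n, a protease inhibitor gene, by 5.56 in 6 of 6 pairs, and Adra1a fell by -2.50 (SE 0.193) with Rem2, Ckmt2 and Klhl14. Macrophage markers rose in 23 of 35 (25 adjusted over the list alone), Cx3cr1 by 2.12 and C1qb by 1.59. The set of macrophage markers had adjusted p = 6.67e-08, and adjusted p = 0.464 with an estimated correlation. Complement genes rose in 14 of 18 (14 adjusted over the list alone), C4b by 2.36 and C2 by 1.35. The set of complement genes had adjusted p = 9.19e-05, and adjusted p = 0.464 with an estimated correlation. Matrix genes rose in 22 of 31 and fell in 1 (25 and 1 adjusted over the list alone), Col6a3 by 0.81 and Col5a2 by 0.66 (adjusted p = 6.95e-05, adjusted p = 0.547 with an estimated correlation). Matrix genes were lower on the contralateral side at 5 weeks than at 1 week. Against the contralateral libraries of the other week Col6a3 (-0.30, adjusted p = 0.177) and Col5a2 (-0.10, adjusted p = 0.553) did not differ. Nerve injury genes rose in 36 of 43 and fell in 2 (37 and 2 adjusted over the list alone; adjusted p = 3.01e-25, adjusted p = 0.00859 with an estimated correlation). Potassium channel genes fell in 21 of 38 and rose in 7 (23 and 7 adjusted over the list alone; adjusted p = 9.19e-05, adjusted p = 0.464 with an estimated correlation). Of 18135 genes tested 7593 differed, 4138 higher and 3455 lower, and 4991 of them differed in the same direction against the contralateral libraries of the other week.

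**Figure D2:**
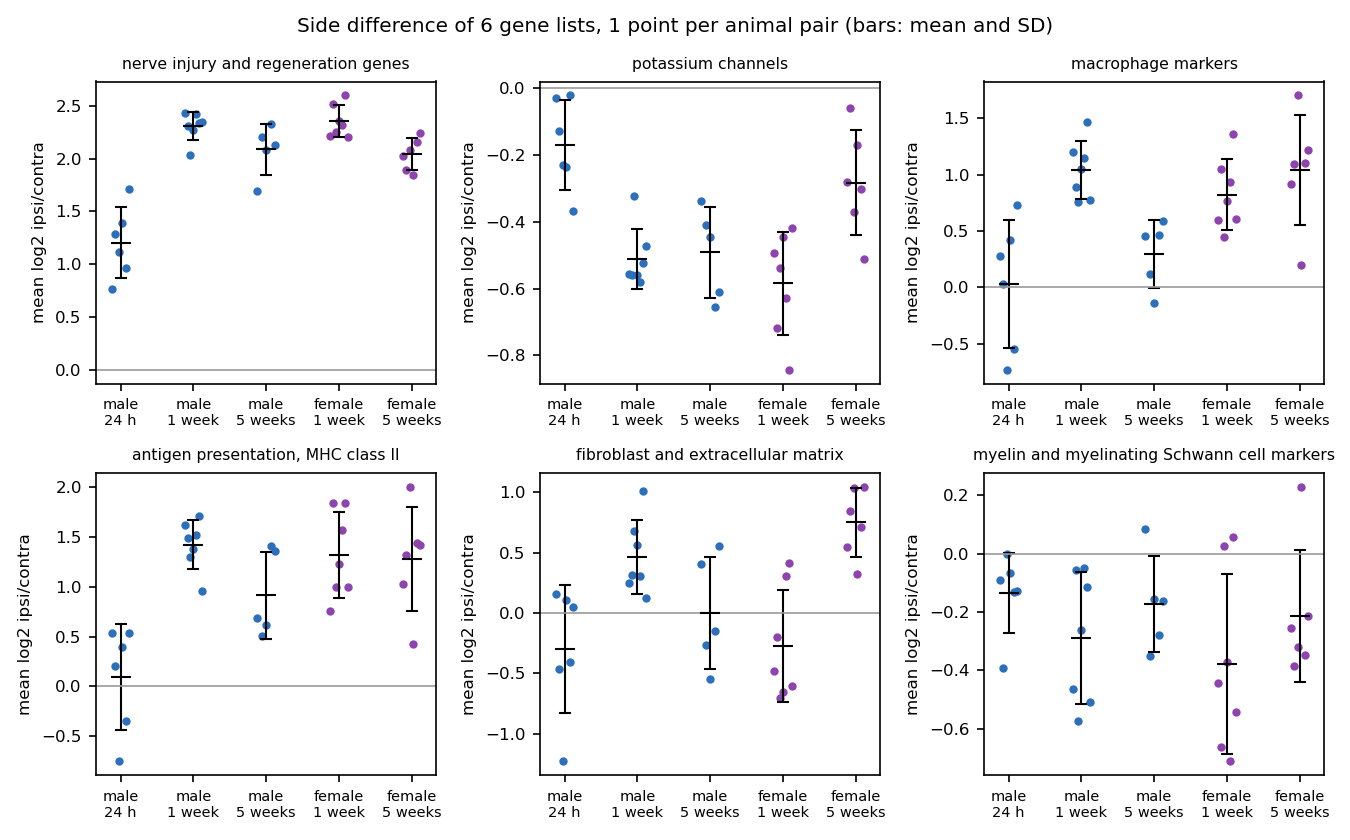
Mean log2 difference between sides over the genes of each list, 1 point per pair.

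Most genes that answered the injury did so in the same direction in both sexes. Among genes tested in both, the log2 fold changes of males and females correlated with r = 0.876 at 1 week, where 3077 genes rose in both (1038 expected by chance), 3164 fell in both (961.7 expected) and 33 changed in opposite directions. At 5 weeks r was 0.847, with 2222 higher in both, 2404 lower in both and 77 opposite. Males at 1 and 5 weeks correlated with r = 0.84 and had 13 genes with opposite calls, whereas females at 1 and 5 weeks correlated with r = 0.792 and had 428, Oprm1, Kcnb2 and Ro60 among them. Early and late male responses were less alike: r = 0.447 between 24 h and 1 week, with 160 genes called in opposite directions. Males at 24 h and females at 1 week, which share a count table, correlated with r = 0.562 and had 90 such genes.

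Between 24 h and 1 week in males Npy and Draxin rose, and Gal, Gap43 and Gfra1 rose further. Many macrophage and cell cycle genes moved up, and many cholesterol genes went back down. The side difference of Npy grew by 9.11 (SE 0.685), of Gal by 3.74, of Draxin by 4.36, of Gap43 by 1.16 and of Gfra1, a receptor for glial cell line-derived neurotrophic factor, by 0.95. Insig1 and Lpin1, of lipid metabolism, were higher at 24 h and no longer at 1 week, with changes of -0.83 and -0.64. Macrophage markers moved up in 19 of 35 (25 adjusted over the list alone; adjusted p = 2.96e-09, adjusted p = 0.209 with an estimated correlation). Cell cycle genes moved up in 29 of 35 (31 adjusted over the list alone; adjusted p = 2.4e-14, adjusted p = 0.195 with an estimated correlation). So did erythrocyte markers (median 2.75, adjusted p = 1.62e-06, adjusted p = 0.209 with an estimated correlation). Neutrophil and mast cell markers (adjusted p = 2.53e-08, adjusted p = 0.195 with an estimated correlation) and B cell markers (adjusted p = 6.7e-05, adjusted p = 0.235 with an estimated correlation) moved with them. Cholesterol genes went down in 15 of 25 and up in 1 (17 and 1 adjusted over the list alone; adjusted p = 1.88e-08, adjusted p = 0.195 with an estimated correlation). Of 19223 genes tested 4418 differed, 2116 toward higher and 2302 toward lower values at 1 week (2394 and 1928 of 4322 with ribosomal RNA genes left out). The 24 h and 1 week male libraries come from different count tables. In females at 1 week, in the same table as the 24 h males, Npy rose by 7.61 and Gap43 by 1.75.

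Between 1 and 5 weeks in males few single genes changed their side difference in the main fit, which ignores the pairs, and more with replicate number as a block. Cdk18, a kinase gene, went from 0.60 to 1.74, a change of 1.14 (SE 0.113, adjusted p = 7.18e-06), the cadherin gene Cdh22 from 0.76 to 2.38, and Chrm2, a muscarinic receptor, from -0.33 to 0.37. Grem1, an inhibitor of bone morphogenetic proteins, went from 1.36 to -0.22 (change -1.58, SE 0.205, adjusted p = 0.000244), Tph2, an enzyme of serotonin synthesis, from 2.24 to 1.09, and Itga7, an integrin gene, changed by -0.41 (SE 0.0522). Macrophage markers went down as a group by a median of -0.76 (adjusted p = 2.37e-11, but adjusted p = 0.302 with an estimated correlation and 0.111 with fry), and no single member passed. Erythrocyte markers did so by a median of -1.57 (adjusted p = 2.83e-07, but adjusted p = 0.302 with an estimated correlation and 0.111 with fry), where 9 of 10 passed over the list alone and none over all genes. Of 18994 genes tested 40 differed, 15 toward higher and 25 toward lower values, and 17 and 14 of 31 with ribosomal RNA genes left out. The number depended on the method: 147 with DESeq2, 499 with replicate number as a block, 24 with the ribosomal RNA share as covariate and 25–50 when 1 library was left out.

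Between 1 and 5 weeks in females Ro60, Oprm1, Kcnb2 and other genes changed direction, and matrix genes moved up on the injured side relative to the other. Ro60 changed by 3.66 (SE 0.169), the lipid kinase gene Pik3c2a by 1.33, Gucy1a2, a guanylate cyclase subunit gene, by 2.27, Unc80, of the sodium leak channel, by 1.61 and Oprm1 by 3.76 (SE 0.234). Tph2 went from 2.44 to 1.03 and Itga7 changed by -0.54, as in males. Matrix genes moved up in 18 of 31 (27 adjusted over the list alone), Col3a1 by 1.39 and Col6a3 by 1.06 (adjusted p = 3.1e-12, adjusted p = 0.913 with an estimated correlation). With the ribosomal RNA share as covariate Col3a1 moved up by 1.05 (adjusted p = 0.233) and Col6a3 by 1.05 (adjusted p = 0.0962). Neither was then called, though the estimate of Col6a3 hardly changed. Potassium channel genes moved up in 11 of 38 and down in 1 (11 and 1 adjusted over the list alone), Kcnb2 by 2.63 and Kcnq3 by 1.32 (adjusted p = 0.000273, adjusted p = 0.913 with an estimated correlation). Of 18135 genes tested 2452 differed, 1388 toward higher and 1064 toward lower values (993 and 1121 of 2114 after removal of an exon length trend), and 676 with the ribosomal RNA share as covariate. Among them are the 428 genes with opposite calls at the 2 weeks, 300 of them lower at 1 week and higher at 5, with a median exon length of 8128 bases against 3266 over all genes. Their score was alike in the contralateral group of 1 week and the ipsilateral group of 5 weeks (0.976 and 0.997), and in the other 2 female groups (0.259 and 0.256).

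**Figure D3:**
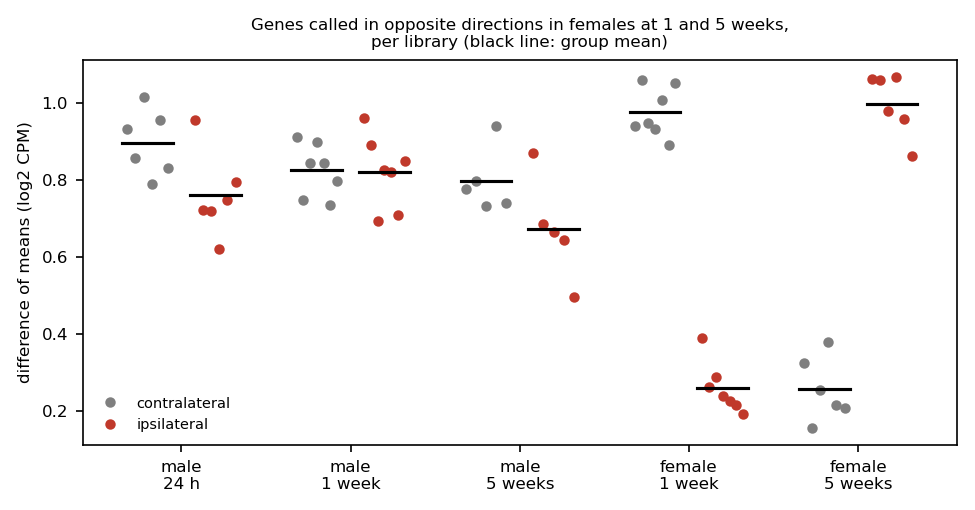
Score of the genes with opposite female calls at 1 and 5 weeks, in each library.

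At 1 week the sexes differed in Ro60, Zbtb41 and Oprm1 among other genes. Ro60 was lower in females (side difference -1.59 against 0.25 in males; difference -1.85, SE 0.14, adjusted p = 8.75e-15), and so were Zbtb41, a zinc finger gene, at -1.65 (SE 0.16), Dmxl1 at -0.73, Gucy1a2 at -0.92 and Oprm1 at -1.78. Leng8 at 0.49 (SE 0.0823) and Nmnat1, an enzyme of NAD synthesis that protects axons, at 0.46 were higher. With the ribosomal RNA share as covariate Leng8 was at 0.32 (SE 0.112, adjusted p = 0.361). As sets, matrix genes (median -0.68, adjusted p = 1e-15, adjusted p = 0.168 with an estimated correlation), erythrocyte markers (median -2.18, adjusted p = 6.79e-14, adjusted p = 0.078 with an estimated correlation) and neutrophil and mast cell markers (median -2.31, adjusted p = 4.87e-12, adjusted p = 0.078 with an estimated correlation) were lower in females. Of 19223 genes tested 218 differed, 83 higher and 135 lower in females (51 and 154 of 205 with ribosomal RNA genes left out), 524 with replicate number as a block and 53, 2 higher and 51 lower, with the ribosomal RNA share as covariate. Of the 218 genes, 141 belong to those with opposite female calls at the 2 weeks, and all female libraries are in a count table other than that of the 1 and 5 week males.

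At 5 weeks Ro60, Oprm1 and Kcnb2 differed between the sexes in the direction opposite to that of 1 week. Ro60 was higher at 1.88 (SE 0.161, adjusted p = 1.38e-12), with Plcxd3 at 1.46 (SE 0.134), Pik3c2a at 0.77, Unc80 at 0.88, Oprm1 at 2.10 and Kcnb2 at 1.49, while the splicing genes Srsf2 at -0.32 and Snrnp70 at -0.45 were lower. Macrophage markers were higher in females by a median of 0.69 (adjusted p = 3.18e-09, but adjusted p = 0.64 with an estimated correlation and 0.149 with fry). Cx3cr1 at 1.34 was the 1 member that passed over the list alone. Over all genes its adjusted p was 0.0589 (0.0276 with DESeq2 and 0.00642 with replicate number as a block). Matrix genes were higher by a median of 0.65 (adjusted p = 1.27e-09, but adjusted p = 0.64 with an estimated correlation and 0.149 with fry), and no single member passed. Over both weeks their median was -0.03 (adjusted p = 0.766), as matrix genes were lower in females at 1 week, and in the contralateral ganglia of females they fell between the weeks. Of 19223 genes tested 403 differed, 298 higher and 105 lower (223 and 132 of 355 after removal of an exon length trend), with 302–556 when 1 library was left out and 695 with replicate number as a block. Of the 403, 216 belong to the genes with opposite female calls, and 142 genes differed between the sexes at both weeks, all in opposite directions. Averaged over both weeks the sexes differed in 3 genes, among them the ribosomal RNA gene Rn45s at -0.77 (SE 0.139, adjusted p = 0.00739). All 3 were also called in that direction at 1 week and 0 of them at 5 weeks. The side difference of Rn45s was -1.37 in females and -0.04 in males at 1 week, and -0.04 and 0.11 at 5 weeks. Of the lists 10 differed over both weeks, and 2 of them also with an estimated correlation. These 2 were erythrocyte markers (median -1.65, adjusted p = 0.0257 with an estimated correlation) and satellite glia markers (median 0.09, adjusted p = 0.0257 with an estimated correlation). Macrophage markers had a median of 0.31 over both weeks (adjusted p = 8.02e-06, adjusted p = 0.731 with an estimated correlation).

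The contralateral libraries also differed between 1 and 5 weeks. In males Ciart and Tef, which follow the circadian clock, were higher at 5 weeks by 2.00 (SE 0.222) and 0.63 (SE 0.0721). Cholesterol genes fell in 16 of 25 and rose in 1 (17 and 1 adjusted over the list alone), Idi1 by -0.69 (SE 0.0598), Hmgcs1 by -0.37 and Nsdhl by -0.40. The set of cholesterol genes had adjusted p = 3.96e-11, and adjusted p = 0.156 with an estimated correlation. In females matrix genes fell in 23 of 31 (28 adjusted over the list alone), Col3a1 by -1.64 and Sparc by -0.50 (adjusted p = 2.08e-24, adjusted p = 0.156 with an estimated correlation). Myelin genes fell in 19 of 22 (19 adjusted over the list alone), Pmp22 by -0.86 (adjusted p = 2.55e-17, adjusted p = 0.294 with an estimated correlation). Ro60, 1 of the 428 genes with opposite female calls, fell by -1.73 and Ncam2, an adhesion gene, by -1.14. In males 2566 of 18994 genes differed, 1390 higher and 1176 lower (1063 and 1426 of 2489 with ribosomal RNA genes left out), and 366 with the ribosomal RNA share as covariate. That share did not overlap between the male weeks (at least 4.11% at 1 week, at most 3.74% at 5 weeks). Lost precision alone could therefore lower the number with the covariate. In females 1940 of 18135 genes differed, 572 higher and 1368 lower. Age and day of sampling may also differ between the weeks and were not part of the fits.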

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

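The crossed batch, the exchange of week labels, a response of the injured ganglion alone and blood were tested only after the results were seen; the library quality axis, the batch test of the macrophage list and the splits of libraries were set down before. Of 175 sets of libraries or pairs, 16 had an outlying value where 8.75 are expected by chance. In libraries these were the ribosomal RNA share of ipsilateral replicate 7 in males at 1 week (3.75%), the total of ipsilateral replicate 1 in males at 5 weeks (18.9 M) and that of contralateral replicate 1 at 24 h (24.0 M). Among list means of pairs they were myelin in pair 2 at 24 h (-0.393); in males at 1 week nerve injury in pair 3 (2.04), opioid genes in pair 1 (-0.386), potassium channels in pair 3 (-0.323), muscle and adipocyte markers in pair 7 (-1.74) and sodium and calcium channels in pair 3 (-0.0537); in males at 5 weeks B cells in pair 3 (-1.45), lipid mediators in pair 3 (-0.287) and muscle and adipocyte markers in pair 5 (-1.57). In females they were cell cycle in pair 6 (0.946) and muscle and adipocyte markers in pair 2 (-2.42) at 1 week, and myelin in pair 4 (0.229) and neutrophil markers in pair 2 (1.603) at 5 weeks. No library was left out for them.

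Some results are listed here because a test of the difference between sexes or times passed. Side differences differed between sexes in 218 genes at 1 week and 403 at 5 weeks, between 24 h and 1 week in 4418, and between 1 and 5 weeks in 40 genes of males and 2452 of females. Gene lists differed in 10, 8, 18, 14 and 6 cases in the same order, and no call among these held with an estimated correlation. At 1 week the sexes differed in Leng8 (0.49), Nmnat1 (0.46), Ro60 (-1.85) and Zbtb41 (-1.65), and at 5 weeks in Ro60 (1.88), Plcxd3 (1.46), Fam193b (-0.46) and Srsf2 (-0.32). From 24 h to 1 week Npy (9.11), Ptpro (1.63), Lpin1 (-0.64) and Insig1 (-0.83) changed. From 1 to 5 weeks Cdk18 (1.14), Cpne9 (1.08), Itga7 (-0.41) and Grem1 (-1.58) changed in males, and Ro60 (3.66), Hecw1 (1.56), Leng8 (-0.84) and Fam193b (-0.57) in females.

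The 428 genes called in opposite directions in females at 1 and 5 weeks had 3 tested readings besides a change of biology with time. A library batch crossed over week and side predicted that the contralateral libraries carry 30 to 70% of the swing; in 159 genes chosen from replicates 1 to 3 they carried 47.1% (40.2 to 52.8 over animals) in the other replicates, which leaves a batch open without proving it. A library quality axis also stays open. These genes moved together within male groups, with a mean correlation of 0.129 against at most 0.00988 in 1000 random sets (percentile 100). The random sets were matched on expression alone, not on exon length. Any set of genes that vary together could exceed them, so this test does not point to library quality. Exchanged contralateral week labels are excluded, as same-numbered ganglia had median correlations of 0.276 and 0.294 at the labelled weeks. The contralateral share had a lower limit of 40.2%, which argues against a response of the injured ganglion alone if no batch is present. A batch in the contralateral libraries could raise that share, so the test does not exclude this reading. Mean scores of the male groups ran from 0.672 (5 weeks, ipsilateral) to 0.897 (24 h, contralateral). The ipsilateral females of 1 week (0.259) and the contralateral females of 5 weeks (0.256) lay below all of them. An injured and an uninjured female group were thus displaced alike, on genes chosen in females. The score cannot say which of the open readings holds, and the female time and sex differences in these genes carry all of them.

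The higher macrophage side difference of females at 5 weeks (median 0.692) was weighed against batch and blood. With the contralateral libraries of the other week it was 0.535 (0.189 to 0.886 over animals). The rule set down before did not name an interval, and by the value alone it counted against a batch. The interval was too wide to tell, so a crossed batch stays open. Over 11 pairs the sexes differed by 0.71 (0.14 to 1.28), and by 0.765 (0.115 to 1.42) with the erythrocyte mean of each pair as covariate. Erythrocyte markers themselves differed the other way (-0.84 in females against males, SE 0.708), so the covariate could hardly lower the macrophage difference. The test therefore does not exclude blood. Sex stays open, as it is tied to the count table, and with an estimated correlation the adjusted p was 0.64.

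In 30 splits of the same libraries (25 for differences across both tables), the real split gave the most genes for all 12 comparisons. Only 1 split, the real one, reached the real number each time. So few splits cannot give a share far under 0.05, and the 12 comparisons were not corrected for. The real split therefore ranked first, but the test cannot exclude chance. The highest other splits gave 490 genes for male 24 h, 1144 for male 1 week, 3053 for male 5 weeks, 2449 for female 1 week and 5932 for female 5 weeks. Most other splits called no gene: 24, 25, 20, 26 and 24 of them in the same order. For differences they gave 64 and 226 between sexes at 1 and 5 weeks, 1905 between 24 h and 1 week, 1 and 26 between weeks in males and females, and 1 and 1 on the contralateral side. Splits that part every pair, as the real one does, numbered 21, 21, 16, 21 and 21 in the 5 comparisons of sides, and the others reached at most 2052, 4541, 2584, 5670 and 4646 genes. For male 5 weeks these 16 are too few for a share under 0.05.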

How the results depend on the processing

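RLE scaling, no filter, a stricter filter, the test without robust fitting, ribosomal RNA genes left out and an exon length trend removed kept all 12 counts within 1.5 times. Some left the larger direction turned: male 1 week gave 4452 higher and 4459 lower with ribosomal RNA genes left out, and female 1 week 4088 higher and 4177 lower with RLE scaling. Fitting the 2 groups alone gave 1597 genes for male 24 h. Replicate number as a block gave 524 and 695 genes between sexes at 1 and 5 weeks and 499 between weeks in males, and DESeq2 gave 147 for the last. Chosen after seeing the data, the ribosomal RNA share as covariate gave 3936 genes for female 1 week and 53 between sexes at 1 week. It gave 24 and 676 between weeks in males and females and 366 for the contralateral ganglia of males. That share did not overlap between the sides of females at 1 week, which also enter differences between sexes and weeks. Nor did it overlap between the weeks in the contralateral ganglia of males. Fewer calls there may therefore reflect lost precision. The mean of both weeks, also chosen after seeing the data, gave 3 genes between sexes in place of those at 1 week and 3 in place of those at 5 weeks. The contralateral libraries of the other week gave 8654 genes for female 1 week and 6663 for female 5 weeks, and reversed Mag at female 1 week (0.03451, adjusted p = 0.865) and Col5a2 (-0.09754, adjusted p = 0.553) and Col6a3 (-0.2983, adjusted p = 0.177) at female 5 weeks, none of them called; Ro60 at female 1 week (0.1404, adjusted p = 0.382) did the same. The mean of both weeks ended the calls of all named genes between sexes, and at 1 week it reversed Leng8 (-0.03595), Pcgf1 (-0.04445), Pabpn1 (-0.01502), Ro60 (0.01834), Zbtb41 (0.0545), Arfgef3 (0.04774), Dmxl1 (0.08932), Plcxd3 (0.1887), Phip (0.07437), Gucy1a2 (0.1513), Pik3c2a (0.1208), Oprm1 (0.1622) and Kcnb2 (0.1351). Of 133 list calls RLE scaling kept 131, the estimated correlation 6 and fry 87. Agreement over genes with mean log2 CPM of at least 1 was 0.904 between sexes at 1 week, 0.878 at 5 weeks, 0.894 between weeks in males, 0.803 in females, 0.549 between male 24 h and 1 week and 0.647 between male 24 h and female 1 week. With 1 library left out the counts were 5685–6679 for male 5 weeks, 302–556 between sexes at 5 weeks, 25–50 between weeks in males (25 without contralateral replicate 2 of males at 5 weeks) and 1736–2353 for the contralateral ganglia of males. The genes of the first 3 kinds of the rule kept their calls under RLE scaling and DESeq2; with the block Mmp13 (adjusted p = 0.113) and Acp5 (adjusted p = 0.0629) lost theirs at 24 h, and between weeks in males Parp1 (adjusted p = 0.0524) and Stat3 (adjusted p = 0.0513 and 0.0525) lost theirs when 1 library was left out. With the ribosomal RNA share as covariate 7 of 16 between sexes at 1 week (Leng8 among them), Carns1 and Art3 between weeks in males (adjusted p = 0.0505 and 0.0553) and Mmp13 at 24 h (adjusted p = 0.0756) lost theirs, and with the crossed block Mmp13 and Acp5 (adjusted p = 0.0919 and 0.13). Of 60 values of list members and of Oprm1 and Kcnb2 that the report names, RLE scaling kept 60 and DESeq2 59. Cx3cr1 between sexes at 5 weeks was called with DESeq2 (adjusted p = 0.0276) and the block (adjusted p = 0.00642). The stricter filter (adjusted p = 0.0489) and the ribosomal RNA share as covariate (adjusted p = 0.0276) called it too. The block (adjusted p = 0.0589) and the 2 groups alone (adjusted p = 0.209) ended the call of Mki67 at 24 h. The ribosomal RNA share ended that of Mag (-0.57, adjusted p = 0.106), Col3a1 (1.05, adjusted p = 0.233) and Col6a3 (1.05, adjusted p = 0.0962). At 24 h limma-voom ended the calls of Gal (adjusted p = 0.102), Sprr1a (adjusted p = 0.0966), Mmp13 (adjusted p = 0.177) and Acp5 (adjusted p = 0.0798), and the 2 groups alone those of Mmp13 (adjusted p = 0.125), Acp5 (adjusted p = 0.199) and Gpx3 (adjusted p = 0.0898). At 5 weeks limma-voom ended those of Serpina3n in males (adjusted p = 0.0981) and Ptprh in females (adjusted p = 0.0573). Without a filter Mmp13 at 24 h (adjusted p = 0.0754) and Parp1 between weeks in males (adjusted p = 0.0643) lost theirs. Genes with opposite differences at both weeks cancel in their mean by construction; for the others the cause was not tested. Totals of 16.9 to 33.5 M counts limit genes of low expression, for which folds against a side near 0 counts are uncertain.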

Other observations

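A group of genes changed its side difference between 1 and 5 weeks in both sexes, which the comparisons of each sex do not show by themselves. Of the 40 genes whose side difference changed in males, 34 changed with the same sign in females, and 17 were also called there in the same direction, against 2.63 expected by chance and 1 in the opposite direction. This overlap was looked at after the lists of genes were seen. Cdk18 grew by 1.14 in males and 0.91 in females, and Cdh22, a cadherin of neurons, by 1.62 and 1.16, and others turned or lost a decrease: Chrm2, a muscarinic acetylcholine receptor, went from -0.33 to 0.37 in males and from -0.30 to 0.59 in females, and Elovl6, which lengthens fatty acids, from -0.30 to 0.03 and from -0.17 to 0.10. Tph2, the enzyme of serotonin synthesis in neurons, went down by -1.15 and -1.42, Grem1, an inhibitor of bone morphogenetic proteins, by -1.58 and -1.34, Itga7, an integrin subunit of laminin binding, by -0.41 and -0.54, and Pdcl3 by -0.59 and -0.69. Within each sex the 2 weeks share a count table, so that sex and table do not enter these changes. The labels do not give the sequencing run of each library, however. A batch crossed over week and side stays open in females and could enter their changes.

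In the contralateral ganglia of males, genes of the circadian clock differed between 5 weeks and 1 week. The prediction was written before their values were looked at, with Ciart and Tef, already seen, left out, and the ipsilateral and female values were part of the same look. If the time of day of collection differed, evening genes would rise over genes of the opposite phase by a median above 0.5 with the same sign on both sides: the difference was 1.67 in contralateral and 1.6 in ipsilateral ganglia, with 8 of 8 and 7 of 8 evening genes higher. Dbp rose by 1.84 (SE 0.268) and Per2 by 1.22 (SE 0.167), and Arntl fell by -0.90 (SE 0.125). Time of day therefore stays open as a cause of part of the male difference between weeks; a shift of the clock itself was not tested, and in females the difference was -0.509 and -0.489.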
